A study of Mus musculus with 9 samples.

How the data were processed

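Round spermatids were obtained from adult mouse testes by sedimentation through an albumin gradient, and purity was judged from cell and nuclear morphology, per the labels' protocols. The cells were cross-linked with formaldehyde and the chromatin was sonicated, immunoprecipitated and sequenced on a NextSeq 500, per the labels' protocols. The labels' protocols name wild-type mice and a line with a disrupted Hrb gene, and which animals gave which library is not given in the sources used here. The labels give 9 libraries, 1 for each of 8 antibodies and 1 of input chromatin, and each antibody formed its own group. The submitters' processing notes list CASAVA, bcl2fastq 2.0, Bowtie 0.12.7, SICER and bedtools, without role or order. The series' design text says that input served to correct for uneven sonication. The deposited lists are named as SICER islands called from unique reads with windows of 200 bp, gaps of 200 bp and a false discovery rate of 0.001. SICER joins neighbouring enriched windows into islands, so the lists mark domains, not summits, and every island is a whole number of windows. How duplicate reads were treated, and the version of SICER, are not given in the sources used here. The deposited lists hold 1 value per island, the count of reads in it, as whole numbers of at least 16 that are not normalized. The input library has no list and entered only through the authors' calling.

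The island counts cover only the part of each library that lies in called islands, from 386930 reads for H3K9me3 to 23673526 for H3K9ac, so library depth is unknown. A deeper library can give a longer list, as can stronger enrichment, and a mark absent from a list is a mark not called there, not a mark shown to be absent. Counts therefore do not compare levels between lists. They were used to rank or filter islands within a list, as reads per kb of the island, and where single regions are described with their reads in several lists, the counts do not show equal or unequal enrichment. Each library is a single replicate, so no test between antibodies was made.

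The sources used here name no genome build. Island ends lie beyond the last gene of the gene table given for this work, of GRCm38.p6, on 10 of 21 chromosomes, and chromosome lengths were not compared. The lists were therefore not taken to be on that assembly, and none of its coordinates were applied. Positions are 1-based and as in the lists. Promoters, annotation classes and gene lists, which had been planned, were not analysed here. The rule planned for named genes (the densest and widest islands of each kind, islands of BRD4 without acetylation or with H3K9me3, and acetylated islands without BRD4) was applied to islands instead of promoters, and the text names some of the islands it gives. The widest islands of the acetylation lists, the densest BRD4 islands with all 6 acetylation lists and without H3K9me3, and the merged regions that stand in for promoters were chosen after the data had been examined. So were the comparisons of X and autosomes at H3K9ac islands matched on read density and the division of H3K9ac islands by H4 marks within deciles of density.

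Islands of 2 lists were counted as overlapping when they shared at least 1 bp. Intervals on shares, differences, ratios, Jaccard indices and rank correlations are percentiles (2.5 and 97.5) over resamples of 10 Mb genome blocks, 1000 draws for each, or 200 for rank correlations. Exact binomial (Clopper-Pearson) intervals are named where used. Random placement moved each island to a random position within the span of islands on its chromosome, 100 times, and the fold is the observed share divided by the mean placed share. Acetylation islands that overlapped were merged into 64910 regions, and each region was scored by how many of the 6 lists it held. The share of a chromosome covered by islands was taken over the span between its outermost islands. For the matched comparison, islands were divided into 10 classes of read density, and the expected share on a chromosome was computed from the autosomal share in each class. The mitochondrial genome was left out of the comparisons between chromosomes. Rank correlations used, for each BRD4 island, the densest overlapping island of the mark.

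Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. The code was tested on simulated data. Simulated BRD4 islands, 39.8% of which were put on H4K5ac islands, were counted at 39.8%. A matched ratio of X made without an effect was returned as 0.983, and a ratio made as 0.5 as 0.464, over 41565 islands. Block intervals held the true share in 94% of simulations, which drew overlaps independently and so did not test clustering along the genome. The overlap of BRD4 with H3K9ac counted with bedtools equalled that counted in windows, 9855 islands.

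Alternatives set before the data were examined were an overlap of at least 50% of the island, overlap of the island's midpoint, islands at or above the median reads per kb of their list, lists of equal number or equal covered length, autosomes only, a circular shift of all islands of a chromosome, islands per Mb, leaving out the pan-acetyl antibody, and read count or island length in the rank correlations. Alternatives added after the data had been examined were placement within 1 Mb, removal of regions called for both BRD4 and H3K9me3, lists of equal number for X, and other forms of matching for X.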

Results

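Chromatin of mouse round spermatids, the haploid germ cells that follow meiosis, was profiled by chromatin immunoprecipitation and sequencing with 8 antibodies and an input library. The antibodies were against BRD4, a bromodomain protein that binds acetylated histones, against trimethylated lysine 9 of histone H3 (H3K9me3), a mark of silent chromatin, and against acetylated histones. The acetylation antibodies recognised H3K9ac, H4K5ac, H4K8ac, H4K12ac, H4K16ac and acetylated H4 without regard to the residue (pan-acetyl H4). Each antibody was used for 1 library, so no difference between antibodies has a replicate check and no p-value is given. The labels name wild-type and gene-disrupted mice and do not say which gave these cells. The lists of enriched islands held 17603 islands for BRD4, 5339 for H3K9me3, 41565 for H3K9ac, 47188 for H4K5ac, 35284 for H4K8ac, 45045 for H4K12ac, 14592 for H4K16ac and 49193 for pan-acetyl H4. They covered 26.6 Mb for BRD4, 8.71 Mb for H3K9me3, 125 Mb for H3K9ac, 113 Mb for H4K5ac, 88.1 Mb for H4K8ac, 119 Mb for H4K12ac, 28.3 Mb for H4K16ac and 116 Mb for pan-acetyl H4. Reads inside islands numbered 1011810 for BRD4, 386930 for H3K9me3, 23673526 for H3K9ac, 8818772 for H4K5ac, 6730816 for H4K8ac, 10387966 for H4K12ac, 1132127 for H4K16ac and 13338416 for pan-acetyl H4. These totals are not library depths, because reads outside islands are not listed. Intervals below are 95% intervals from resampling of 10 Mb blocks of the genome unless named as exact binomial intervals. They cover sampling of the genome or counting error only, not the variation between animals or libraries.

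The first comparison asked which histone marks BRD4 islands lay on. BRD4 islands lay mainly on acetylated chromatin. H3K9ac islands overlapped 56.0% of them (54.8 to 57.2), pan-acetyl H4 islands 53.0% (51.8 to 54.3), H4K12ac islands 52.1% (50.8 to 53.4), H4K5ac islands 51.7% (50.4 to 53.0) and H4K8ac islands 48.5% (47.3 to 49.7). H4K16ac islands overlapped 26.2% (25.2 to 27.2) and H3K9me3 islands 0.898% (0.648 to 1.20). At least 1 of the 6 acetylation lists overlapped 61.9% of BRD4 islands (60.7 to 63.2), against a mean of 11.2% when the islands were placed at random within their chromosomes. The excess over random placement was 7.72-fold for H3K9ac, 7.16-fold for pan-acetyl H4, 7.12-fold for H4K12ac, 7.19-fold for H4K5ac, 8.70-fold for H4K8ac and 12.9-fold for H4K16ac, the shortest of the acetylation lists. For H3K9me3 it was 1.50-fold (1.08 to 2.01). This overlap was concentrated in the densest decile of BRD4 islands, 4.83% of which lay on H3K9me3. In the other deciles 0.227% to 0.795% did, against a placed mean of 0.598% for all BRD4 islands. When each island was instead moved by no more than 1 Mb, so that chance overlap within acetylated neighbourhoods was counted, the excess of the acetylation lists ranged from 4.26-fold for H4K5ac to 6.91-fold for H4K16ac, and that of H3K9me3 was 2.02-fold.

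**Figure D1:**
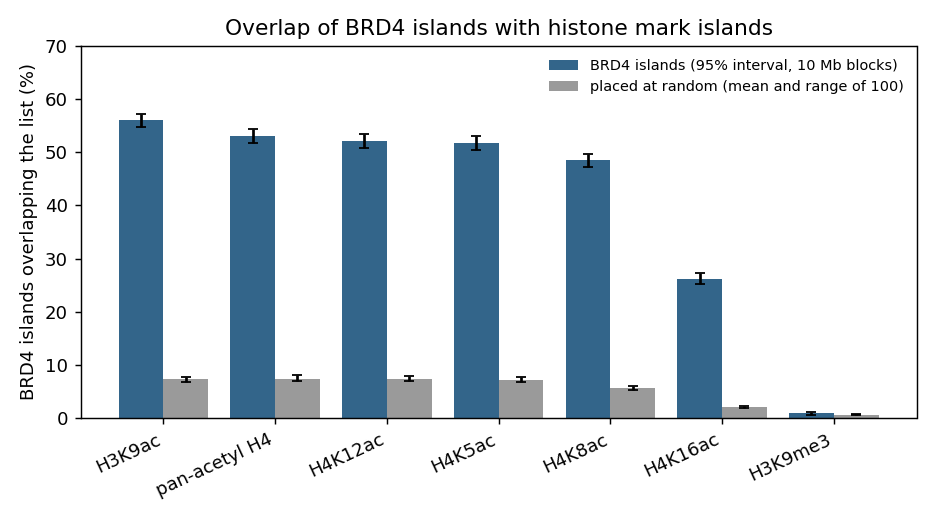
Percent of the 17603 BRD4 islands that overlap each list of mark islands by at least 1 bp (blue, with 95% intervals from 10 Mb blocks) and the same percent for BRD4 islands placed at random (grey, mean and range of 100 placements). The bars for H3K9ac, pan-acetyl H4, H4K12ac, H4K5ac and H4K8ac stand between 48.5% and 56.0%, H4K16ac at 26.2% and H3K9me3 at 0.898%.

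The overlap with H3K9ac exceeded that with pan-acetyl H4 by 2.94 percentage points (2.38 to 3.41) and that with H4K8ac by 7.48 points (6.92 to 7.96). This order depended on the length of the lists. When each mark was cut to its 14592 islands with most reads, the number in the H4K16ac list, H4K12ac overlapped 39.9% of BRD4 islands, H3K9ac 39.4%, pan-acetyl H4 39.0%, H4K5ac 38.8% and H4K8ac 37.7%, and H4K16ac kept its 26.2%. With only the islands at or above the median read density of each list, pan-acetyl H4 overlapped 58.2% and H3K9ac 57.7%. Seen from the marks, BRD4 islands overlapped 31.1% of H4K16ac islands (30.0 to 32.4), 22.6% of H4K8ac islands, 21.3% of H3K9ac islands, 18.6% of H4K12ac islands, 17.9% of H4K5ac islands and 17.5% of pan-acetyl H4 islands. Between lists of 14592 islands H4K16ac was the lowest instead, since the other acetylation lists had BRD4 at 40.9% to 42.7% of islands, 9.76 to 11.6 points above H4K16ac. The islands kept in those lists were also wider, with medians of 3400 to 4800 bp against 1800 bp for H4K16ac.

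The number of acetylation marks at a region was set against BRD4 next. BRD4 was most frequent where every acetylation antibody had called an island. Overlapping acetylation islands were merged into 64910 regions, and BRD4 lay on 5.70% of the regions with 1 list (5.31 to 6.10), 5.41% of those with 2, 5.48% with 3, 7.15% with 4, 17.9% with 5 (17.0 to 18.8) and 54.9% with all 6 (53.5 to 56.6). Regions with more lists were also wider, with a median of 1200 bp for 1 list and 7000 bp for 6, and random placement of BRD4 gave 1.87% and 6.75%. Set against the placed shares, which grow with width, the observed share was 3.04 times as high with 1 list and 2.48 times with 2. It was 2.25 times as high with 3, 2.76 with 4, 5.11 with 5 and 8.14 with 6. By length, BRD4 islands covered 0.484% of the genome with no acetylation island, 2.98% of the length under 1 list, 10.5% under 5 and 36.4% under 6. Among BRD4 islands themselves the largest classes were those with no acetylation island, 38.1% or 6700 islands, those with all 6 lists, 24.6%, and those with every list but H4K16ac, 21.7%.

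**Figure D2:**
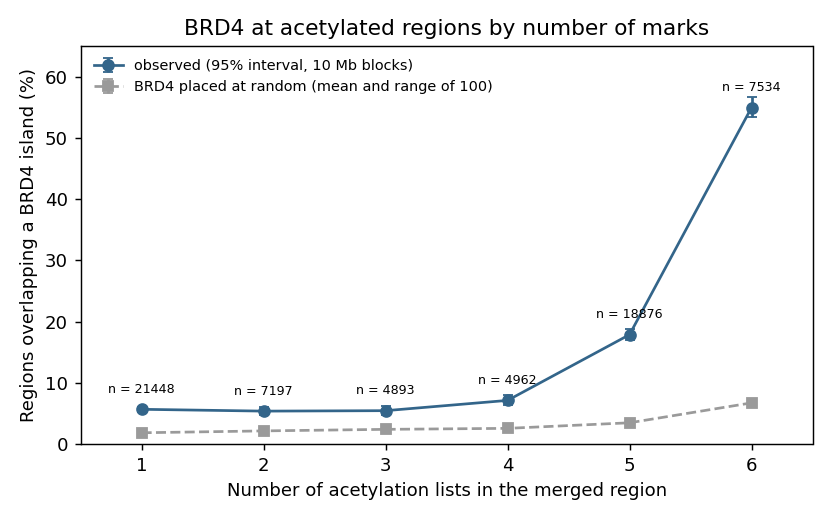
Percent of merged acetylation regions that overlap a BRD4 island, by the number of acetylation lists in the region (blue, 95% intervals from 10 Mb blocks), with BRD4 islands placed at random in grey (mean and range of 100 placements). The observed share stays between 5.41% and 7.15% for 1 to 4 lists and reaches 17.9% for 5 and 54.9% for 6.

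H3K9ac islands were then divided by whether an H4 acetylation island lay on them. Over all H3K9ac islands the difference in BRD4 was largest for H4K16ac: BRD4 lay on 53.1% of the 7763 H3K9ac islands with H4K16ac (51.7 to 54.7) and on 14.0% of the 33802 without it (13.2 to 14.8), a difference of 39.1 points (37.8 to 40.6). The difference was 16.8 points for H4K8ac, 15.6 for H4K5ac, 14.5 for H4K12ac and 12.4 for pan-acetyl H4. Part of this followed the H3K9ac islands themselves, since BRD4 lay on 9.21% to 10.6% of those in the lower 6 deciles of H3K9ac read density and on 70.8% in the highest. Their median width also rose, from 1200 bp in the lowest decile to 7000 bp in the highest. Wider islands meet BRD4 or an H4 list more often by 1 bp. Width was not separated from density, nor matched in the comparisons within deciles. Within the highest decile on autosomes, BRD4 lay on 76.6% of the islands with H4K16ac (exact interval 75.2 to 78.0) and 44.5% of those without it (40.3 to 48.7). In deciles 6 to 9 on autosomes H4K16ac had the smallest difference instead, with BRD4 on 37.9% of the islands with it and 20.4% of those without. Single deciles, over all chromosomes, gave smaller gaps for H4K16ac than this pool. BRD4 lay on 20.6% with it and 16.3% without in decile 7, 33.6% and 24.3% in decile 8, and 47.4% and 34.1% in decile 9. In the pooled deciles 6 to 9 on autosomes BRD4 lay on 25.5% of the islands with H4K5ac and 2.32% of those without. The shares were 25.8% and 3.13% for H4K8ac, 25.2% and 2.46% for H4K12ac and 25% and 3.36% for pan-acetyl H4. In these deciles 351 H3K9ac islands had no H4 acetylation island at all, and 2.56% of them had BRD4 (exact interval 1.18 to 4.81), against 24.9% of the 15454 that had one (24.2 to 25.6). In the lower 5 deciles on autosomes the direction was the opposite, with BRD4 at 14.6% of the islands without H4 acetylation (13.6 to 15.7) and 8.62% of those with it (8.18 to 9.08). For H4K16ac it was not, with BRD4 at 11.5% of the islands with the mark (9.16 to 14.3) and 9.99% of those without (9.57 to 10.4).

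Across BRD4 islands, BRD4 read density rose modestly with that of the mark beneath. Spearman's rho over islands that shared a list was 0.339 for H4K16ac (0.313 to 0.368, 4607 islands), 0.306 for H4K5ac, 0.289 for pan-acetyl H4, 0.277 for H4K12ac, 0.271 for H4K8ac and 0.247 for H3K9ac (0.225 to 0.266, 9855 islands). These are correlations across islands of the same libraries, which are not independent replicates. With island length in place of read density, rho fell to 0.116 for H3K9ac and 0.197 for H4K5ac and was 0.313 for H4K16ac.

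Single regions are given by position only, since the sources used here name no genome build for the files, and genes were not analysed here. The widest BRD4 island lay on chromosome 17 from 27454601 to 27488000, held 1634 BRD4 reads and overlapped all 6 acetylation lists. It sat inside the widest acetylation island of the H4K5ac, H4K8ac, H4K12ac and pan-acetyl H4 lists, which ran from 27427201 to 27488000 in each. There the read density was 305 reads per kb for H3K9ac, 248 for pan-acetyl H4, 197 for H4K12ac, 173 for H4K5ac and 149 for H4K8ac, each over its own island. The fifth widest BRD4 island, on chromosome 16 from 10782601 to 10800600, held 994 BRD4 reads and also overlapped all 6 acetylation lists, with an H3K9ac density of 557 reads per kb. The other 3 of the 5 widest BRD4 islands overlapped H3K9me3. The one on Y from 2847401 to 2872400 also overlapped all 6 acetylation lists. The one on chromosome 11 from 3080601 to 3100200 lacked H3K9ac, and the one on Y from 2874401 to 2902400 lacked H3K9ac, H4K12ac and pan-acetyl H4. Strong acetylation did not always come with BRD4. The H3K9ac islands of highest density that carried all 6 acetylation marks and no BRD4 island lay on chromosome 14 from 25175001 to 25179200, with 611 H3K9ac reads per kb, and on chromosome 15 from 82677201 to 82690200, with 532. The densest BRD4 islands with all 6 acetylation lists and no H3K9me3, a class chosen after its values were seen, lay on chromosome 14 from 51682401 to 51685200, with 186 BRD4 reads per kb, and on chromosome 11 from 58115601 to 58116600, with 177.

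The sex chromosomes were compared with the 19 autosomes, since X is silenced as a whole chromosome during meiosis and carries separate chromatin afterwards. H4 acetylation and BRD4 were scarce on X, and H3K9ac was less reduced there. H3K9ac islands covered 3.15% of X against 3.93% to 7.02% of the autosomes, a ratio of 0.637 to the pooled autosomes (0.531 to 0.755). The ratio was 0.223 for pan-acetyl H4 (0.181 to 0.268), 0.184 for H4K8ac (0.149 to 0.225), 0.151 for H4K12ac (0.121 to 0.185) and 0.144 for H4K5ac (0.114 to 0.176). H4K16ac had 44 islands on X, which covered 0.0404% of it against 0.724% to 2.0% of the autosomes, a ratio of 0.0346 (0.0139 to 0.0710). BRD4 had 184 islands on X and a ratio of 0.156 (0.101 to 0.228), and H3K9me3 a ratio of 0.342 (0.137 to 0.658). X ranked below every autosome in all 8 lists. With 14592 islands per mark the ratio was 0.629 for H3K9ac (0.505 to 0.759) and 0.0556 to 0.105 for the H4 marks other than H4K16ac. Counted as islands per Mb the ratios were higher, at 0.288 for H4K8ac, 0.254 for H4K12ac, 0.223 for H4K5ac and 0.335 for pan-acetyl H4. With islands at or above the median read density they were 0.621 for H3K9me3 and 0.0613 for H4K16ac. The islands on Y spanned only 2.79 Mb, with 3 to 22 islands per list, so Y was not compared.

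**Figure D3:**
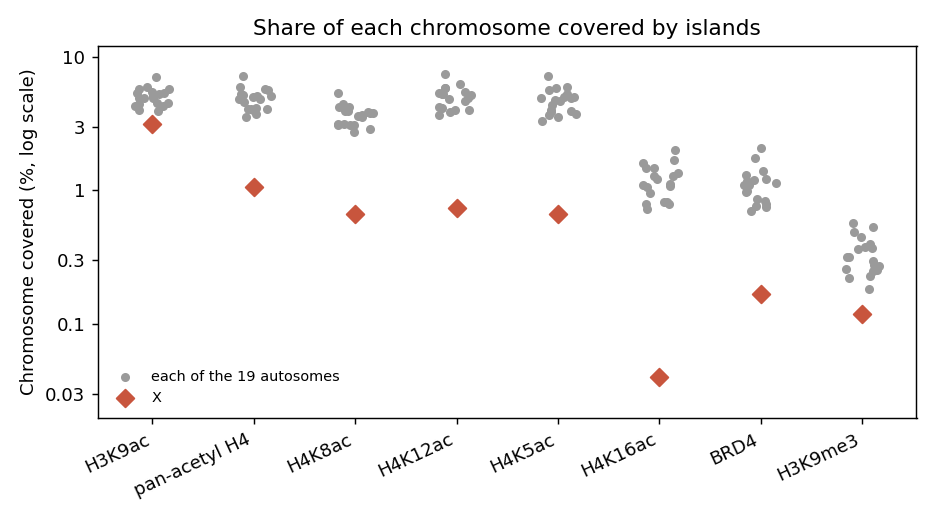
Percent of each chromosome covered by islands of each list, on a log scale, for the 19 autosomes (grey points) and X (red diamonds). X lies below every autosome in each list, at 3.15% for H3K9ac and 0.0404% for H4K16ac.

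The scarcity on X was also present at H3K9ac islands of equal read density. The 1767 H3K9ac islands on X were compared with autosomal ones matched on H3K9ac read density. H4K16ac lay on 1.47% of the X islands against 17.9% expected, a ratio of 0.0824 (0.0530 to 0.116), while single autosomes ranged from 0.865 to 1.14. BRD4 lay on 5.38% against 20.9% expected, a ratio of 0.258 (0.191 to 0.321), with autosomes from 0.782 to 1.27. The ratio was 0.468 for H4K5ac (0.426 to 0.504), 0.473 for H4K8ac (0.427 to 0.514), 0.492 for H4K12ac (0.461 to 0.523) and 0.641 for pan-acetyl H4 (0.614 to 0.667), each below its lowest autosome, which stood at 0.925 or more. H3K9me3 had a ratio of 1.63 (0.209 to 3.89) on 16 X islands, inside the range of the autosomes, 0.297 to 2.13. In the highest decile of H3K9ac density the H4 marks parted. H4K5ac lay on nearly every autosomal island there, so a weaker H4K5ac signal on X could go unseen, unlike for the shorter H4K16ac and BRD4 lists. H4K5ac lay on 96.8% of the 124 X islands (exact interval 91.9 to 99.1) and 99.9% of the 4029 autosomal ones, H4K16ac on 14.5% (8.84 to 22.0) and 86.1% (84.9 to 87.1), and BRD4 on 27.4% (19.8 to 36.2) and 72.1% (70.7 to 73.5).

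**Figure D4:**
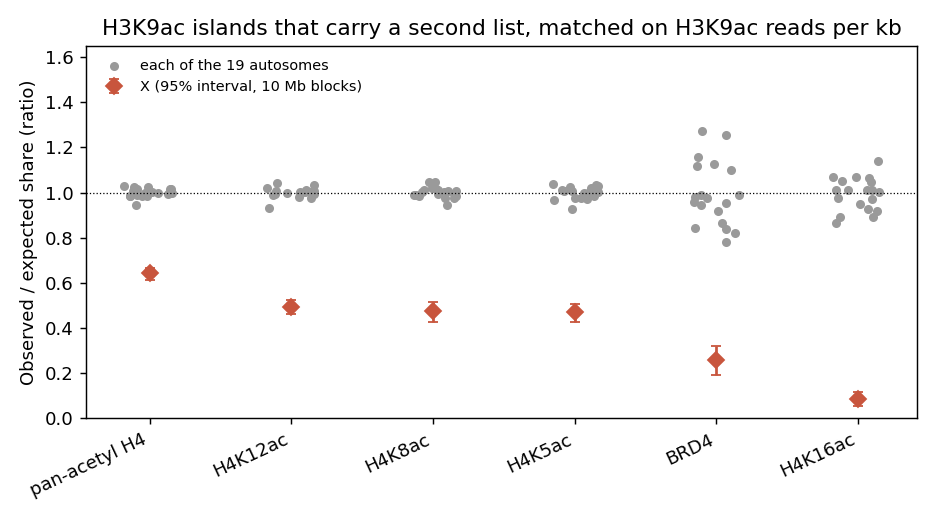
Ratio of the observed share of H3K9ac islands that carry BRD4 or an H4 acetylation list to the share expected from autosomal islands of equal H3K9ac read density, for the 19 autosomes (grey points) and X (red diamonds, 95% intervals from 10 Mb blocks). X lies at 0.641 for pan-acetyl H4, 0.258 for BRD4 and 0.0824 for H4K16ac, below every autosome in each of the 6 lists drawn.

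H3K9me3 islands were set against the other lists as a silent counterpart. Of these islands 87.8% (85.8 to 89.6) overlapped no other list, about the share that random placement gave, 88.5%, a ratio of 0.992 (0.970 to 1.01). The share with any acetylation was likewise 1.05 times the placed share (0.884 to 1.22), and single marks departed from it in both directions. H3K9me3 and H3K9ac, which occupy the same residue, overlapped less often than under random placement, with H3K9ac on 4.33% of H3K9me3 islands or 0.617 times the placed share (0.507 to 0.727). H4K12ac, on another histone, stood at 0.603 times the placed share (0.476 to 0.753) and H4K5ac at 0.684 (0.541 to 0.839). The depletion was thus not particular to lysine 9 of H3. The intervals of H4K8ac, 0.924 (0.709 to 1.18), and pan-acetyl H4, 0.838 (0.680 to 1.02), included no change. BRD4 lay on 3.0% of H3K9me3 islands, 1.53 times the placed share (1.13 to 1.99), and H4K16ac on 4.57%, 2.36 times (1.71 to 3.10). The overlap with BRD4 was concentrated in the densest decile of H3K9me3 islands, at 16.9%. It was 0.749% to 1.69% in deciles 1 to 7, below the placed mean of 1.96% for the whole list, and 3.0% and 2.43% in deciles 8 and 9. Of the 20 densest BRD4 islands, 11 overlapped H3K9me3. How the overlap of H3K9me3 with H4K16ac was spread over read density was not computed. The 3 densest H4K16ac islands all overlapped H3K9me3. The island on chromosome 9 from 35112601 to 35113400 was called for BRD4, with 543 reads, and for H3K9me3, with 544, and in no other list. On chromosome 2 from 98502201 to 98503200 there were 1075 reads for BRD4, 1083 for H3K9me3, 1030 for H4K8ac and 1051 for H4K16ac, and the other lists had no island there. The widest H3K9me3 islands lay on chromosome 3 from 25416201 to 25456400, which also overlapped H4K8ac, and on chromosome 11 from 3049401 to 3080200, which overlapped all 6 acetylation lists.

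The similarity of all pairs of lists was measured as the Jaccard index, the shared length divided by the joint length. H3K9ac, H4K5ac, H4K8ac, H4K12ac and pan-acetyl H4 formed a close set, with a median index of 0.606 (0.598 to 0.613) and a highest value of 0.656 between H4K12ac and pan-acetyl H4. H4K16ac had a median index of 0.147 (0.141 to 0.151) with these lists, although 60.4% to 67.4% of its length lay within each of them. BRD4 had a median index of 0.0986 (0.0944 to 0.103) with the 6 acetylation lists, highest with H4K16ac at 0.131 and with H4K8ac at 0.115. H3K9me3 had a median of 0.00442 (0.00292 to 0.00643) with all other lists. When every list was cut to the same covered length of 8.71 Mb, the index of H4K16ac with the other acetylation lists rose to 0.264, that of H3K9me3 with all other lists rose to 0.0101, and that among the other acetylation lists fell to 0.544.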

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

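The BRD4 list was the only one of the 8 with islands on the mitochondrial genome, which entered no comparison between chromosomes. The 2 islands, from 1 to 6600 and from 10801 to 16200, held 6563 and 5788 reads, 12351 in all or 1.22% of the reads in BRD4 islands. The other 7 lists had 0 islands there. These islands were among the 3 densest of the BRD4 list, and neither overlapped an acetylation island.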

How the results depend on the processing

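Of 179 recomputed values, 98 stayed within the interval of the main value, 81 moved beyond it and 0 reversed. Shares and Jaccard indices have no value of no change to cross, so only folds, ratios and correlations were open to reversal. The order of the marks, which did change between settings above, is not among the 179. H4K16ac and H3K9me3 kept all their islands in lists of equal number. Their BRD4 overlaps there, 26.2% and 0.898%, and X ratios, 0.0346 and 0.342, were thus unchanged by construction. For shares of islands or regions the interval of the main value was the exact binomial interval, which is narrower than the block interval printed above. Some values counted as moved therefore lie inside the block interval. Placement within 1 Mb, removal of regions called for both BRD4 and H3K9me3, lists of equal number for X and the changes of matching were chosen after seeing the data. The intervals are narrow because islands are many, and the cause of the shifts below was not tested except where the alternative itself removes islands or overlaps. No paired analysis was possible because each group has 1 library. The promoter windows, gene lists, annotation classes and promoter-based placement were not run.

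Requiring at least 50% of the BRD4 island to be covered lowered its overlap to 51.1% for H3K9ac, 48.6% for H4K5ac, 46.3% for H4K8ac, 49.3% for H4K12ac, 23.7% for H4K16ac, 49.9% for pan-acetyl H4 and 56.6% for any acetylation. The midpoint gave 51.7%, 48.4%, 46.1%, 49.4%, 23.4%, 49.8% and 57.1% in that order, and 0.750% for H3K9me3. Islands at or above the median density in both lists gave 57.7% for H3K9ac, 57.5% for H4K5ac, 53.2% for H4K8ac, 57.6% for H4K12ac, 31.1% for H4K16ac, 58.2% for pan-acetyl H4 and 1.29% for H3K9me3. Mark lists of equal number gave 39.4% for H3K9ac, 38.8% for H4K5ac, 37.7% for H4K8ac, 39.9% for H4K12ac, 39.0% for pan-acetyl H4 and 44.5% for any acetylation. They gave BRD4 at 6.31% of merged regions with 1 list and 59.9% with all 6. Autosomes alone, removal of regions called for both BRD4 and H3K9me3, and circular shifts moved no recomputed value beyond its interval. No overlap of H3K9me3 with BRD4 or an acetylation list was recomputed without those regions. Placement within 1 Mb changed the excess to 4.98-fold for H3K9ac, 4.26-fold for H4K5ac, 5.43-fold for H4K8ac, 4.30-fold for H4K12ac, 6.91-fold for H4K16ac, 4.42-fold for pan-acetyl H4 and 2.02-fold for H3K9me3. For H3K9me3 islands, 50% coverage gave 2.32% with BRD4 and 9.14% with any acetylation, and the midpoint 2.38% and 9.08%.

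The median Jaccard index at equal covered length was 0.544 among the 5 longest acetylation lists, 0.264 for H4K16ac with them, 0.124 for BRD4 with acetylation and 0.0101 for H3K9me3 with all lists. Denser islands gave 0.631 for the first of these and 0.0860 for BRD4. Counted as islands per Mb, the ratio of X to autosomes was 0.223 for H4K5ac, 0.288 for H4K8ac, 0.254 for H4K12ac and 0.335 for pan-acetyl H4. With lists of equal number it was 0.0665, 0.0834, 0.0556 and 0.105 in that order, and with denser islands 0.135 for H4K8ac, 0.621 for H3K9me3 and 0.0613 for H4K16ac. Denser islands of the second list lowered the matched ratio of X to 0.396 for H4K5ac, 0.352 for H4K8ac, 0.372 for H4K12ac and 0.480 for pan-acetyl H4. Rank correlations by island length were 0.116 for H3K9ac, 0.197 for H4K5ac, 0.238 for H4K8ac, 0.199 for H4K12ac, 0.313 for H4K16ac and 0.195 for pan-acetyl H4. By read count they were 0.186 for H3K9ac, 0.316 for H4K8ac and 0.392 for H4K16ac. Library depth is unknown, so how far it limits each list could not be measured.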

Other observations

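H4K16ac differed from the other acetylation marks in how much of it stood alone. Of its 14592 islands, 25.2% overlapped no other acetylation list, against 14.1% for H3K9ac, 9.46% for H4K5ac, 7.86% for pan-acetyl H4, 7.27% for H4K12ac and 2.17% for H4K8ac. BRD4 lay on 3.37% of the H4K16ac islands that stood alone and on 40.5% of those that shared another acetylation list. H4K5ac, H4K12ac and pan-acetyl H4 islands that stood alone had BRD4 at 3.09% to 3.72%, H4K8ac islands at 4.84%, and H3K9ac islands that stood alone at 12%. H4K16ac islands that stood alone had a median of 29.5 reads per kb and the others 36.9. Islands that stood alone were also less dense in the other lists, with 51.7 against 100 for H3K9ac, 37.3 against 55.6 for H4K5ac, 32.5 against 54.3 for H4K8ac, 37 against 58.8 for H4K12ac and 42 against 67.5 for pan-acetyl H4.

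The share of BRD4 on pan-acetyl H4 islands of X was also below that of matched autosomal islands, at 8.54% against 13.9% expected, a ratio of 0.615 (0.480 to 0.773) with autosomes from 0.756 to 1.33. At these islands the ratio was 0.275 for H4K16ac, 0.790 for H4K5ac, 0.831 for H4K12ac and 0.867 for H4K8ac, and 1.20 for H3K9ac. For H3K9me3 it was 5.0 on 34 islands, above the autosomes, 0.3003 to 2.40, with an interval of 0.980 to 11.7. Among pan-acetyl H4 islands without H4K16ac the ratio was 0.587, with autosomes from 0.686 to 1.42. On X, 26 H3K9ac islands carried H4K16ac, and 73.1% of these had BRD4 (exact interval 52.2 to 88.4), while of the 1741 without H4K16ac 4.37% had it (3.45 to 5.43).

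The tests below were chosen after the results they measure had been seen. H4 acetylation and BRD4 islands are scarcer on X than H3K9ac islands, which are themselves below every autosome. A lower dose of X in haploid cells lowers all libraries alike. At X islands matched on H3K9ac density the highest ratio among the 5 H4 lists and BRD4 was 0.641, for pan-acetyl H4, below every autosome. This does not decide on dose, because matching removes it only where a list follows H3K9ac density closely. BRD4 density did so only modestly, with a rho of 0.247 over the BRD4 islands that overlap H3K9ac. No such correlation was computed for the H4 lists. Fewer reads can also drop an island below the calling threshold. H3K9me3, with 1.63 (0.209 to 3.89) on 16 islands, was left out of this test because its interval decides nothing. Sequence that is hard to map was set against the same islands, where H3K9ac reads did map. The highest upper bound of those ratios was 0.667 and the lowest autosome of any of these lists 0.782. These islands are not wholly unmappable, but a partial loss of reads meets the same limit of matching and is not decided either. Weak X islands called only because H3K9ac has more reads in islands are argued against by the 14592 islands of most reads in each list, whose ratio was 0.629 for H3K9ac (0.505 to 0.759) and at most 0.105 for the H4 marks. A candidate explanation is that X carries less H4K16ac and BRD4 relative to H3K9ac than autosomes do in these cells, a hypothesis from 1 library per antibody. It is not particular to these, since the matched ratios of H4K5ac, H4K8ac and H4K12ac, 0.468 to 0.492, were below every autosome as well. Library depth, the quality of each antibody and other cell types in the fraction were not tested, and the design gives no group that tests a biological explanation.

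BRD4 islands without any acetylation island, 38.1% of the list, are the second pattern. Of these islands 36.5% (exact interval 35.4 to 37.7) reached the median read density of the BRD4 list, 34 reads per kb. That median lies close to the lower quartile, 29.3, so reaching it does not make a strong call, and weak calls stay open. The share without acetylation fell from 60.9% in the lowest decile of density to 20.3% in decile 9 and 24.1% in the highest. Such islands were thus more frequent at low density but not confined to it. Acetylation islands that stop just short account for few, since 16.3% lay within 1 kb of one and the median gap was 7200 bp. High-copy sequence cannot be told apart here: 0.776% overlapped H3K9me3, but choosing islands without acetylation calls had already removed sequence called in every list. Acetylation below the calling threshold, other acetylated residues and binding without acetylation stay open, and no biological explanation was tested.

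The 158 BRD4 islands that overlap H3K9me3 are the third pattern. They hold 5.63% of the reads in BRD4 islands and 85 of them lie in the densest decile of the list. If they were high-copy sequence read with any antibody, the densities of BRD4 and H3K9me3 would rise together closely and most would be called in all lists. Rho across them was 0.876 (0.792 to 0.921), above the 0.247 to 0.339 of the acetylation lists. H4K16ac lay on 46.8% of them, with a rho to BRD4 of 0.814 there and 0.323 at islands without H3K9me3. But 13.9% of them overlapped all 6 acetylation lists and 32.9% none. The rho goes with signal that does not depend on the antibody. The missing calls decide nothing, because input entered the calling and sequence that is high in input too can be left uncalled in some lists. Such signal therefore cannot be told apart from true joint occupancy or from a wider range of densities at these islands.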
